A study of Mus musculus with 8 samples.

How the data were processed

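Peak lists of 6 ChIP libraries were analysed, 2 each for SOX10, H3K27ac and H3K27me3 in 1 mouse melanocyte line, grouped by the antibody and the replicate number in the sample titles. The 2 input libraries had no lists of their own and enter only as the background of the authors' calls. Per the labels' protocols, each antibody was used in separate experiments on crosslinked, sonicated cells. P values in the text measure the placement of regions or sites within these lists, not variation between cultures. No test across the libraries was made, and a permutation test of 2 libraries against 2 could not pass 0.05.

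The authors called peaks separately in each library with MACS 1.4.2, per the file headers, at a p cutoff of 1e-05 and with at most 1 tag kept per position. Positions refer to the mm9 build, per the submitters' processing notes, and the aligner is not given in the sources used here. Per the file headers, the SOX10 and H3K27ac lists used a local background from windows of 1000 and 10000 bp of the input, and the H3K27me3 lists had the local background turned off. The assumed distance between tags of both strands was 225 and 212 bp for SOX10, 50 and 51 bp for H3K27ac and 200 bp for H3K27me3, per the file headers, with tags of 35 and 36 bp for SOX10 and 51 bp for the histone marks. For H3K27ac that distance is about the tag length, so tags were hardly moved towards the fragment centre and peaks can be narrower or split. The larger of the ChIP and input libraries was scaled to the smaller, per the file headers, and the genome size was set to 1910000000 bp for SOX10 and 1870000000 bp for the histone marks.

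Each deposited list gives positions, the count of tags in the peak, -log10 of the MACS p multiplied by 10, the fold enrichment at the summit over the background, and an FDR in percent. The deposited tag counts are whole numbers, and no normalised signal was used. The deposited -log10 p values are multiplied by 10, so the authors' cutoff is 50. The fold enrichment is the authors' ratio of ChIP tags to background, per the file headers. The authors' FDR is in percent, per the file headers. In the H3K27me3 lists 99.97% and 99.99% of the strongest decile of peaks had an FDR above 1%, so an FDR filter removes the strongest H3K27me3 regions. Of all SOX10 peaks, 31.1% in replicate 1 and 79.5% in replicate 2 had an FDR above 1%, and of their strongest decile 31.1% and 18.0%. Of all H3K27ac peaks it was 1.13% and 0.798%, and of their strongest decile 11.3% and 7.98%. The few H3K27ac peaks that an FDR filter removes are therefore from the strongest decile. These scores are the peaks' own values and were used to describe, rank or filter peaks. 1 column title in 1 SOX10 list was damaged, and columns were read by position.

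Depth differed between antibodies. Of 14170747 and 14592541 SOX10 tags, 6440395 and 8985699 were kept after duplicate removal, with 55% and 38% redundant. For H3K27ac 45583056 and 44416913 were kept (4% and 3% redundant), and for H3K27me3 67060647 and 71987481 (16% and 23%). The inputs kept 12059585 and 42782172 tags. A median SOX10 peak held 21 and 29 tags and a median H3K27ac peak 30 in both replicates. The effect of depth on the lists was not tested. Wilson intervals are at 95% and cover counting error only.

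Peaks of both replicates were merged where they shared at least 1 bp, and merged regions with at least 1 peak of each replicate were the consensus regions. The summit of a consensus region is that of its peak with the highest fold, and its log2 fold is the mean of both replicates' highest. Overlaps needed at least 1 bp. Expected overlaps came from 1000 random placements of the regions within the stretch of the same chromosome that any list covers, or at 20 to 200 kb from each region's own position. Alternatives and distances used 200 placements, and 100 or 50 where at least 50% of the shorter region had to be shared. Differences in log2 fold or width between sets of sites were tested with 100000 permutations of the site labels, or 10000 for H3K27ac regions and for alternatives, two-sided. The SE given with such a difference is its SD over these permutations, that is, its spread with no true difference. Coverage at the SOX10 summit and 500 bp away was compared with an exact McNemar test. Benjamini-Hochberg adjustment was made within each table of tests.

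The input background under a peak was recovered as the Poisson mean at which its tags give its p. In the H3K27me3 lists, which have no local background, it was within 1% of the input tags over the genome size at 96.8% and 95.2% of peaks. On simulated peaks the error was at most 0.00911%. For SOX10 and H3K27ac it gives the larger of the genome-wide and local input background, so its floor is the genome-wide level, and sites within 5% of it are called at the floor. Tests were run on simulated data first. With 0%, 10% and 50% of the 4159 SOX10 sites moved onto H3K27ac regions, 2.34%, 12.1% and 50.8% overlapped, and 1, 20 and 20 of 20 runs had p below 0.05. For SOX10 enrichment by H3K27ac state, simulated with 400 sites, 100 runs without a difference gave 0 with p below 0.05. The number of runs was then raised to 1000, of which 37 had p below 0.05. A simulated difference of 0.5 was estimated as 0.50 over 50 runs. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

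The tests, comparisons and alternatives were fixed before the data were examined, except those named as chosen later. Alternatives were stricter thresholds, other overlap rules and placements, numbered chromosomes only, merged histone regions, each replicate left out and same-numbered libraries only. Regions named in the text are the 10 of each antibody with the highest mean fold and the 10 widest, the rule set for the case that genes cannot be assigned, of which examples are given. No genome sequence or gene annotation of the mm9 build was used here, and the gene table at hand is of the GRCm38.p6 assembly. Genes, promoters, the 16 gene lists and sequence motifs planned for the SOX10 sites were therefore not analysed here, and regions are given by position only. Chromosome densities, coverage around summits, distances, clusters and the recovered background were added after the lists were seen.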

Results

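The data were chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from melan-Ink4a-Arf-1, an immortalised mouse melanocyte line derived from embryonic skin of animals mutant for the tumour suppressor locus Cdkn2a. The culture medium held the phorbol ester TPA and cholera toxin, and what these do to the lists was not tested. ChIP-seq recovers DNA bound to an antibody's target, sequences it and finds places with more sequence tags than an input library made without antibody. 3 antibodies were used, each in 2 libraries from independent experiments per the labels' protocols. SOX10 is a transcription factor of the neural crest that melanocytes need for their development and survival. H3K27ac, acetylated lysine 27 of histone H3, marks active promoters and enhancers. H3K27me3, the trimethylated form, is made by Polycomb repressive complex 2 and marks repressed chromatin. The study's title asks by which mechanisms SOX10 acts on functional classes of genes in melanocytes, and the peak lists show where SOX10 sites lay relative to both histone marks. Tags kept after removal of duplicates were 6440395 and 8985699 for SOX10 replicates 1 and 2, 45583056 and 44416913 for H3K27ac, and 67060647 and 71987481 for H3K27me3. SOX10 peaks were called against an input of 12059585 kept tags, and peaks of both histone marks against an input of 42782172. Positions are in the mm9 build of the mouse genome.

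SOX10 had the fewest peaks, 8011 ± 2266 per library (SD, n = 2), against 72554 ± 3007 for H3K27ac and 75125 ± 6375 for H3K27me3. The SOX10 lists held 6409 and 9613 peaks, and the list with more peaks came from the library with more kept tags. For both histone marks the reverse held, with 70427 and 74680 H3K27ac peaks and 79632 and 70617 H3K27me3 peaks in replicates 1 and 2. H3K27ac peaks were the narrowest, with a median width of 292 ± 1.4 bp, H3K27me3 peaks had a median of 662 ± 13.4 bp and SOX10 peaks of 922 ± 55.2 bp (SD, n = 2). H3K27me3 peaks covered the most sequence, 73.7 ± 6.62 Mb per library, against 27.9 ± 1.67 Mb for H3K27ac and 8.04 ± 2.82 Mb for SOX10. The authors' fold enrichment at a peak's summit, its tags over the input background, had a median of 9.72 ± 0.962 for SOX10, 7.84 ± 0.184 for H3K27ac and 4.92 ± 0.156 for H3K27me3 (SD, n = 2). Peak numbers, widths and folds of different antibodies came from different depths, tag sizes and calling settings, so they describe these lists only.

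Both replicates of each antibody found many of the same places. Of the SOX10 peaks of replicate 1, 65.4% (95% Wilson interval 64.2 to 66.5%) overlapped a peak of replicate 2, and 43.6% (42.6 to 44.6%) did so in the other direction. The shares were 64.0% and 59.6% for H3K27ac and 46.8% and 52.6% for H3K27me3. Random placement of the peaks gave 0.785% and 0.528% for SOX10, 2.22% and 2.08% for H3K27ac, and 6.37% and 7.23% for H3K27me3, and none of 1000 placements reached the observed share (one-sided permutation p = 0.001 for each, the smallest they can give). Strong peaks were shared most: of the strongest decile of SOX10 peaks by the authors' p, 99.1% of replicate 1 and 94.8% of replicate 2 were found again, against 38.0% and 17.4% of the weakest decile. Regions with at least 1 peak of each replicate, called consensus regions from here on, numbered 4159 for SOX10, 36655 for H3K27ac and 30517 for H3K27me3. Their median widths were 1150, 547 and 1373 bp. Across consensus regions, which are not independent replicates, the log2 fold enrichments of both libraries correlated with r = 0.720 for SOX10, 0.562 for H3K27ac and 0.528 for H3K27me3. Keeping only peaks with the authors' false discovery rate (FDR) of at most 1% lowered the mean shared percentage of H3K27me3 peaks from 49.7% to 17.2%. That filter removed 99.97% and 99.99% of the strongest decile of H3K27me3 peaks in replicates 1 and 2.

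SOX10 sites lay at H3K27ac regions far more often than random positions did. Of the 4159 SOX10 consensus sites, 2212 overlapped an H3K27ac consensus region, 53.2% (95% Wilson interval 51.7 to 54.7%), where random placement on the same chromosome gave 97.5 sites, or 2.34%. This was a 22.7-fold excess, and none of 1000 placements exceeded 130 sites (two-sided permutation p = 0.002, the smallest they can give, and 0.002 after Benjamini-Hochberg adjustment over 6 overlap tests). Placement within 200 kb of each site's own position, which keeps the local density of H3K27ac, gave 250.2 sites and an 8.84-fold excess. Among all pairs of a SOX10 list with an H3K27ac list, between 48.8% and 53.7% of SOX10 peaks overlapped (SD 2.02 percentage points over 4 pairs, which share libraries). SOX10 peaks that the other replicate lacked overlapped less often, 30.6% (28.7 to 32.5%) in replicate 1 and 39.3% (38.0 to 40.6%) in replicate 2, against 50.7% and 52.2% of shared peaks. The share went with the input background recovered under the site: of the 647 sites with that background at its genome-wide floor in both replicates, 17.0% lay at H3K27ac regions. Sites without an overlap were still near: of these 1947 sites, 15.9% lay within 1 kb of an H3K27ac region, where random placement on the same chromosome gave 3.43% and placement within 200 kb gave 5.32%. Within 50 kb lay 58.1%, where these gave 27.8% and 45.9% (two-sided permutation p = 0.01 for each from 200 placements, 0.01 or 0.0114 after adjustment over 8 tests). Placed positions could themselves overlap a region, which raises these expected shares.

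As the H3K27ac regions were called, the SOX10 summit was covered less often than its flanks. H3K27ac consensus regions covered 16.1% of SOX10 summits, 34.6% of positions 500 bp to the left and 34.4% of positions 500 bp to the right. At 976 sites the position 500 bp to the left was covered and the summit was not, and at 207 sites the reverse held (exact McNemar p = 1.01e-119). To the right the numbers were 975 and 213 (exact McNemar p = 8.34e-117). Each H3K27ac replicate alone showed it, with 12.8% of summits covered in replicate 1 and 15.4% in replicate 2, against 33.8% and 35.2% of positions 500 bp to the left. At 869 sites, 20.9% of all, the summit was uncovered with an H3K27ac region within 1 kb on both sides. H3K27me3 regions covered 0.337% of SOX10 summits. Requiring the summit inside the region therefore lowered the share at H3K27ac from 53.2% to 16.1%, still above the 1.08% of random placement (two-sided permutation p = 0.01). Merging H3K27ac regions less than 1 kb apart, which fills such gaps, raised the share of covered summits from 16.1% to 49.2%, and the positions at 500 bp then exceeded the summit by 1.27 percentage points, from 18.4. The H3K27ac calls, made with a tag distance of 50 or 51 bp, can be split. With single peaks of SOX10 replicate 2 as sites the difference was 10.6 percentage points.

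**Figure D1:**
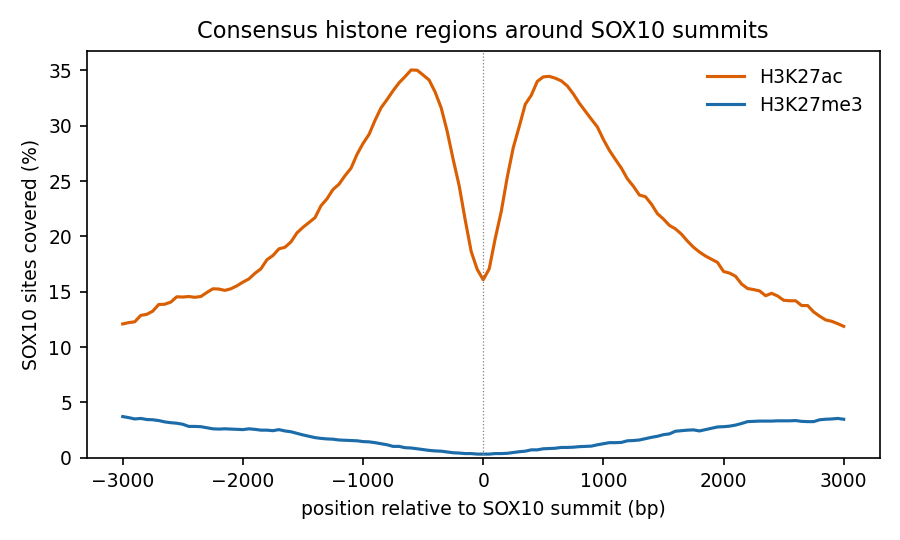
Percentage of the 4159 SOX10 consensus sites (y axis) whose position at a given distance in bp from the SOX10 summit (x axis, in steps of 50 bp) fell in an H3K27ac (orange) or H3K27me3 (blue) consensus region. H3K27ac coverage was 16.1% at the summit and 34.6% and 34.4% at 500 bp to either side, and H3K27me3 coverage was 0.337% at the summit.

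SOX10 sites at H3K27ac regions had a lower fold enrichment and were wider than the rest. Their mean log2 fold enrichment was 3.41 (SD 0.64 over 2212 sites), against 3.62 (SD 0.50 over 1947 sites) elsewhere, a difference of -0.20 ± 0.02 (SE; two-sided permutation p = 1e-05 from 100000 permutations, the smallest they can give, and 1e-05 after adjustment over 5 tests). It was -0.21 in replicate 1 and -0.19 in replicate 2. Their median width was 1303 bp, against 1033 bp, where a wider site also meets an overlap of 1 bp more easily. The direction depended on the measure. The input background under a site, recovered from the authors' tags and p, had a median of 1.91 times the genome-wide level in replicate 1 and 1.99 in replicate 2 at sites with H3K27ac, and 1.26 and 1.27 at the others. Summit height, the fold enrichment multiplied by that background, was higher with H3K27ac, by 0.38 ± 0.02 on the log2 scale (SE; permutation p = 1e-05), and the authors' -log10(p), multiplied by 10 in the lists, was higher by 25.7 (permutation p = 1e-04, the smallest that 10000 permutations give). Ranked by fold enrichment, 82.9% of the lowest decile of SOX10 sites lay at H3K27ac regions, 36.5% of decile 7 and 56.2% of the highest. Ranked by summit height, the share was 27% in the lowest decile and 80.5% in the highest, higher in each decile than in the one below.

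**Figure D2:**
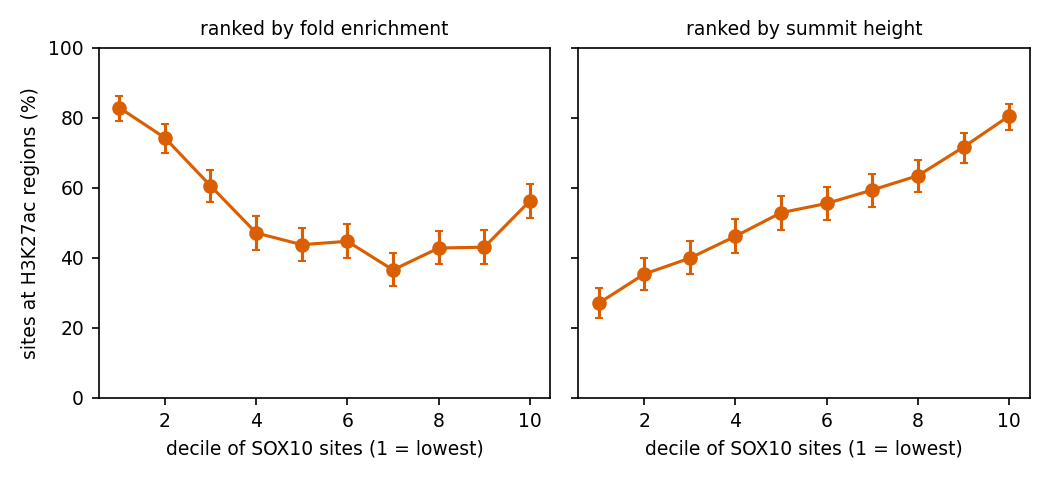
Percentage of SOX10 consensus sites at H3K27ac regions (y axis) in each decile of the sites (x axis, 415 or 416 sites each, 1 the lowest), ranked by fold enrichment on the left and by summit height on the right. Bars are 95% Wilson intervals, and the share runs from 82.9% to 56.2% on the left and from 27% to 80.5% on the right.

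The strongest SOX10 site lay on chromosome 2 at 29361522 to 29362762, with a fold enrichment of 68.3 ± 0.141 (SD, n = 2), and overlapped an H3K27ac region. It was followed by a site on chromosome 10 at 52549865 to 52551433, with 52.5 ± 8.18, and another on chromosome 2 at 102713018 to 102714152, with 52.3 ± 4.58 (SD, n = 2), both at H3K27ac regions. Of the 10 sites with the highest fold enrichment, from 43.2 to 68.3, 8 lay at H3K27ac regions and none at H3K27me3. The exceptions were on chromosome 15 at 59019439 to 59020602 (46.7 ± 12.4) and on chromosome 3 at 141172097 to 141173627 (45.3 ± 3.73; SD, n = 2). Of the 10 widest SOX10 sites, 9 lay at H3K27ac regions. The widest was on chromosome 5 at 143578272 to 143585977, 7706 bp long with a fold enrichment of 9.03 ± 1.80 (SD, n = 2). The exception, on chromosome 17 at 39979541 to 39985980, had a fold enrichment of only 2.07 ± 0.354 (SD, n = 2) with 6636 tags in replicate 2, so the input was also high there.

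From the side of acetylation, 3540 of the 36655 H3K27ac regions, 9.66%, overlapped a SOX10 site. These had a median width of 737.5 bp, against 532 bp for the other 33115, and a median fold enrichment of 9.33 against 8.53. The difference in mean log2 fold enrichment was 0.14 ± 0.01 (SE; two-sided permutation p = 1e-04 from 10000 permutations, the smallest they can give). Of the narrowest decile of H3K27ac regions 4.34% had a SOX10 site, and of the widest decile 20.6%, where a wider region also offers more room for an overlap. The H3K27ac region with the highest fold enrichment, on chromosome 7 at 51727757 to 51729715 (28.1 ± 3.89; SD, n = 2), overlapped a SOX10 site. So did 7 of the 10 highest in all, with folds from 21.1 to 28.1. The second highest, on chromosome 17 at 87599397 to 87604057 (25.3 ± 1.76; SD, n = 2), did not. Of the 10 widest H3K27ac regions, 6.55 to 14.0 kb long, 3 overlapped a SOX10 site and 4 lay on chromosome 6. The widest spanned 14042 bp on chromosome 6 at 82973114 to 82987155, with a fold enrichment of 13.1 ± 0.170 (SD, n = 2).

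SOX10 sites were scarce at H3K27me3 regions. 55 of 4159 sites, 1.32% (95% Wilson interval 1.02 to 1.72%), overlapped one, where random placement gave 158.1 sites and at least 116. This was 2.87-fold fewer than placement on the same chromosome gave (two-sided permutation p = 0.002, the smallest 1000 placements can give). It was 5.51-fold fewer than placement within 200 kb gave, which came to 303.0 sites. Among all pairs of a SOX10 list with an H3K27me3 list, 1.96 ± 0.331% of SOX10 peaks overlapped (SD over 4 pairs). Of the 4104 sites without an overlap, 51.5% lay within 50 kb of an H3K27me3 region. Placement on the same chromosome gave 29.2% (two-sided permutation p = 0.01), and placement within 200 kb gave 51.9% (p = 0.667 by permutation). Within 1, 5 and 10 kb lay 2.56%, 10.9% and 19.3%. Placement on the same chromosome gave 5.27%, 9.41% and 13.1%, and placement within 200 kb 10.1%, 17.7% and 24.4% (two-sided permutation p = 0.01 for each). Placed positions could themselves overlap a region, which raises these expected shares. The values therefore cannot tell whether sites without an overlap lay nearer to or further from H3K27me3 than its local density gives. Of the 55 sites, 12 were on chromosome 6 and 8 had an input background over 10 times the genome-wide level with a fold enrichment between 2.07 and 4.31. The strongest was on chromosome 3 at 36306345 to 36307194, with a fold enrichment of 31.9 ± 0.318 (SD, n = 2), chosen after its value was seen. Both marks together were found at 7 sites, 0.168% (0.0816 to 0.347%), H3K27me3 without H3K27ac at 48, H3K27ac without H3K27me3 at 2205 and neither mark at 1899, 45.7% (44.2 to 47.2%). Without SOX10 replicate 1, using all peaks of replicate 2, the share at H3K27me3 was 2.00%, still below the 3.54% of random placement. Sites without H3K27ac made up 48 of the 55, and placement was not run for such sites alone. How much of the scarcity follows from the sites at H3K27ac regions therefore cannot be told.

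The regions of both histone marks overlapped less than random positions did. Of 36655 H3K27ac regions, 712 overlapped an H3K27me3 region, 1.94% (95% Wilson interval 1.81 to 2.09%), where random placement gave 1257 (two-sided permutation p = 0.002, the smallest 1000 placements can give). Placement within 200 kb gave 2688. These 712 H3K27ac regions had a lower fold enrichment, with a median of 7.30 against 8.64 and a log2 difference of -0.24 ± 0.01 (SE; two-sided permutation p = 1e-04). Chromosome 6 held 268 of them, where 10.3% of H3K27ac regions overlapped H3K27me3. All H3K27ac regions on chromosome 6 had a median fold of 7.21, against 8.65 elsewhere. The fold difference was not computed without that chromosome, so how much of it comes from there cannot be told. Without chromosome 6, 1.30% of H3K27ac regions overlapped, where placement gave 2.73%, so the scarcity did not rest on that chromosome. The share depended on the H3K27me3 library: it was 4.69% with replicate 1 alone, where placement gave 5.50%, and 2.14% with replicate 2 alone, where placement gave 4.84%.

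The 10 H3K27me3 regions with the highest fold enrichment, from 46.6 to 73.0, included no H3K27ac region. The highest, on chromosome 2 at 98501962 to 98504769, had 73.0 ± 0.615 (SD, n = 2). 4 of the 10 overlapped SOX10 peaks with an input background over 10 times the genome-wide level, and the authors called H3K27me3 peaks without a local background, so a high fold there can hold input signal as well as H3K27me3. A further 3 lay on sequences with no position in a chromosome, 1 of them assigned to chromosome 1 and 2 to none. The widest H3K27me3 region spanned 51171 bp on chromosome 11 at 3049328 to 3100498, with a fold enrichment of 42.8 ± 0.615 (SD, n = 2). It was also called without a local background, so its fold can hold input signal too, and the input there was not examined. The other 9 of the 10 widest, down to 25448 bp, had folds between 7.87 and 12.2. They included 38338 bp on chromosome 6 at 52172111 to 52210448 (12.2 ± 1.24), 34673 bp on chromosome 1 at 90121834 to 90156506 (11.04 ± 0.156) and 33933 bp on chromosome 15 at 102751748 to 102785680 (10.4 ± 1.08; SD, n = 2). None of the 10 widest overlapped an H3K27ac region, 1 overlapped a SOX10 site and 5 lay on chromosome 6.

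Chromosomes 6 and X stood apart. Chromosome 6 held 5995 of the 30517 H3K27me3 regions, 41.0 per Mb, where the other numbered chromosomes ranged from 6.52 to 18.9 per Mb with a median of 9.30. Both libraries showed it, with 82.7 and 83.3 peaks per Mb against medians of 27.1 and 23.2 on the other numbered chromosomes. H3K27ac and SOX10 regions were not in excess on chromosome 6, with 17.8 and 1.89 per Mb inside ranges of 9.39 to 27.4 and 1.31 to 2.16. H3K27ac regions on chromosome 6 had a lower median fold, 7.21 against 8.65, and a larger median width, 675 against 542 bp. X held few regions of any antibody: 43 SOX10 sites, 29 H3K27ac regions and 12 H3K27me3 regions, or 0.268, 0.181 and 0.0747 per Mb. The numbered chromosomes had medians of 1.72, 15.96 and 9.48 per Mb. None of the SOX10 sites on X overlapped an H3K27ac region. No test across samples was made of these densities, which differed in the same direction in both libraries of each antibody.

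**Figure D3:**
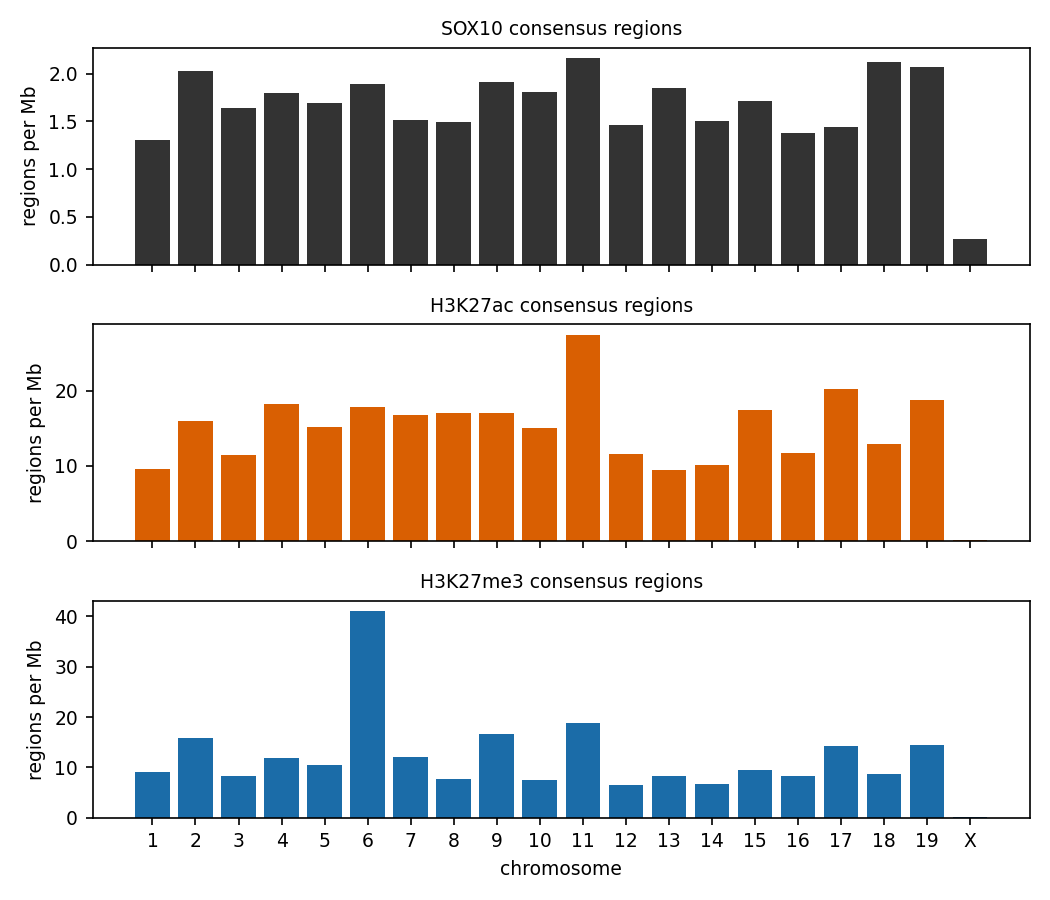
Consensus regions per Mb (y axis) on chromosomes 1 to 19 and X (x axis) for SOX10, H3K27ac and H3K27me3, each panel with its own scale from 0. H3K27me3 regions reached 41.0 per Mb on chromosome 6 and at most 18.9 on the other numbered chromosomes, and X had 0.268, 0.181 and 0.0747 regions per Mb for the 3 antibodies.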

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

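Over 18 results, 106 alternatives were computed, 78 fixed before the data were examined and 28 chosen after seeing the data (without chromosome 6, differently numbered libraries, sites split by input background, summit height, coverage around summits, and densities on chromosomes 6 and X). SOX10 sites stayed above random placement at H3K27ac regions in all 15 alternatives (16.1 to 61.9%) and below it at H3K27me3 regions in all 16 (0.0715 to 3.85%), and H3K27ac regions stayed below it at H3K27me3 regions in all 13 (0.175 to 5.23%), with permutation p below 0.05. Leaving out each replicate gave 43.7 to 61.9%, 1.39 to 2.00% and 2.09 to 4.69%. The lowest shares at H3K27me3 regions, 0.0715% and 0.175%, came from the filter for FDR at most 1%. That filter removes the strongest H3K27me3 regions, so it adds little to the result. The lower SOX10 log2 fold enrichment at H3K27ac regions (-0.20) reversed with the -log10(p) of the lists as the measure (25.7), with summit height (0.38) and at sites with the input background at its floor (0.14). The cause was not tested for -log10(p). It kept its direction in the other 7, and leaving out each replicate gave -0.20 to -0.18. Keeping a listed -log10(p), multiplied by 10, of at least 100 left 1250 SOX10, 17534 H3K27ac and 11878 H3K27me3 consensus regions, with median widths of 1276, 769 and 2182 bp. With FDR at most 1% there were 1398 SOX10 and 6794 H3K27me3 regions, and median widths were 1217.5, 540 and 869 bp for SOX10, H3K27ac and H3K27me3. Fewer peaks enter by construction. Replicate overlap kept its excess in all 15 alternatives over the 3 antibodies. Replicate numbers are shared between antibodies, but nothing in the labels says that they pair libraries: same-numbered pairs gave 51.2% (SOX10 at H3K27ac), 1.98% (SOX10 at H3K27me3) and 3.55% (H3K27ac at H3K27me3), and differently numbered pairs 50.8%, 1.93% and 3.65%. Alternatives listed for genes, promoters and motifs were not run, since no mm9 annotation or genome was used here. What depth limits in the SOX10 lists was not tested.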

Other observations

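Chosen only after their results were seen were the tests of neighbouring sites and acetylated stretches, of the input background on chromosome 6 and along it, of halved SOX10 lists alone and of a tag ratio common to all lists. SOX10 sites lay in groups. Of 4159 sites, 26.6% had another within 25 kb, where random placement gave 8.26% and placement within 200 kb of each site's own position gave 17.7% (one-sided permutation p = 0.001 for both, the smallest 1000 placements can give). Sites with such a neighbour lay at H3K27ac regions in 66.7% of cases, against 48.3% of the rest. Linking sites at most 25 kb apart gave 1 group of 6 sites, on chromosome 2 between 90315140 and 90377470, with 4 sites at H3K27ac regions. It also gave 4 groups of 5 sites. 1 of these, on chromosome 11 between 70642671 and 70704400, had all 5 sites at H3K27ac regions and held a site with a fold enrichment of 48.1, among the 10 highest.

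Long acetylated stretches often held SOX10 sites. Linking H3K27ac regions at most 10 kb apart and ranking the stretches by acetylated length, 154 of the top 200 (77%, 95% Wilson interval 70.7 to 82.3%) held at least 1 SOX10 summit, against 1483 of the other 10598 (14.0%, 13.3 to 14.7%). The top 200 were far longer, with a median of 51.6 kb against 1.49 kb, and per 100 kb of stretch they held fewer SOX10 summits, 2.496 against 3.30. The longest acetylated stretch lay on chromosome 7 between 152122548 and 152362928, with 132 H3K27ac regions over 240.4 kb and 1 SOX10 summit. Of the top 200, 25 lay on chromosome 6.

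H3K27me3 regions on chromosome 6 numbered 41.0 per Mb, 2.17 times the highest other numbered chromosome (1.66 to 2.65 times in 4 alternatives). More H3K27me3 with equal input DNA is argued against by the implied input background on chromosome 6, which was 1.29 and 1.32 times that of the other numbered chromosomes in the H3K27ac lists, where single other chromosomes ranged from 0.980 to 1.03 (1.37 in both SOX10 lists, which add little, since another chromosome reached 1.32 there). A raised part under 50% of chromosome 6 is argued against by all 15 bins of 10 Mb lying above 1.1 in both H3K27ac lists, at 1.23 to 1.35 in replicate 2, where the highest of 226 bins elsewhere was 1.07. By H3K27me3 density 80% of bins on chromosome 6 were over 1.5 times the median bin elsewhere, which lay between the bounds set beforehand. Of 227 bins elsewhere 26.9% were over that level. The H3K27me3 excess was uneven, since the lowest bin on chromosome 6 had 8.1 regions per Mb, against a median of 9 elsewhere. A candidate explanation is extra copies of chromosome 6 in the cells, with H3K27me3 called against a genome-wide background. Raising the background there by the H3K27ac ratio lowered the density to 24.1 per Mb, still above the highest other (18.9). Per library it fell to 45.3 in replicate 1, under its highest other of 46.7, and to 55.5 in replicate 2, over its 38.8. Peaks on chromosome 6 were kept down to a listed -log10(p), multiplied by 10, of 50, though the replicate 2 list held none under 60.75. The cutoff was therefore looser for chromosome 6 in replicate 2, which can raise the 55.5 and the consensus densities given here. A rise of 1.5 times gave 19.6 per Mb, and 1.56 times was the smallest that brought chromosome 6 to the highest other. The recovered background cannot fall below the genome-wide level, so the H3K27ac ratio may understate the difference in input DNA. A rise by that ratio may therefore be too small. Whether copies account for the whole excess therefore cannot be told apart from a further H3K27me3 gain. A difference between cell lines was not tested, since the design has no second line.

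X had 0.268 SOX10, 0.181 H3K27ac and 0.0747 H3K27me3 regions per Mb, below the lowest numbered chromosome for each antibody and in all 3 alternatives of each, but the ratio to the lowest moved, from 0.0192 to 0.0323 and 0.0399 for H3K27ac with 1 library left out, and under the stricter p from 0.204 to 0.0741 for SOX10, from 0.0192 to 0.0127 for H3K27ac and from 0.0115 to 0.0270 for H3K27me3. A single copy of X for 2 of each numbered chromosome is argued against as the whole cause for the histone marks: with all tags on the numbered chromosomes halved, their median density stayed above that on X by up to 12.9 times (8.79 times at least in the 4 histone lists). The 12.9 came from H3K27me3 replicate 2 and can be too high, since halved peaks were kept down to a listed value of 50 and that list held none under 60.75. For SOX10 alone the halved lists came to 1.15 and 1.38 times the density on X, so a single copy may account for the SOX10 part. As the only cause, a lower share of X in the DNA common to all lists would give similar tag ratios that match X. These were 0.30 to 0.34 in the histone lists and 0.45 to 0.48 in the SOX10 lists, which differ by 1.6 times. The ratios take sites on X to be otherwise as dense as on the numbered chromosomes, and the lists differ in input, depth and background setting. They therefore cannot tell whether a lower share of X is part of the cause. The recovered input background on X, looked at after the lists were seen, was below every numbered chromosome. It was 1.00 in both SOX10 lists (lowest numbered 1.27 and 1.30) and 1.17 and 1.11 in the H3K27ac lists (1.21 and 1.13). That goes with less X in the input DNA, but few peaks on X carry it and its floor hides the size, and no test was made. Open and untested are few sites for both marks on X in these cells and differences in gene density.

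The lower SOX10 fold enrichment at H3K27ac regions (-0.20 on the log2 scale) may come from a higher input background under those sites, since the fold divides by it. At the 647 sites with the background at its floor in both replicates, the 110 with H3K27ac had a mean log2 fold of 3.98 and the 537 without 3.84, a difference of 0.14 ± 0.05 (SE; two-sided permutation p = 0.00257), so the lower fold was not seen there. Only 17.0% of these sites were at H3K27ac regions, against 53.2% of all. Why the input is higher at acetylated sites was not tested, and no biological explanation was tested.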
